A study of Mus musculus with 3 samples.

How the data were processed

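Whole-genome bisulfite sequencing, in which bisulfite converts unmethylated cytosines and leaves methylated ones readable, was made from 3 libraries of mouse bone marrow cells (strain C57BL/6, 11 weeks old), 1 library for each of 3 stages of osteoclast differentiation. Per the labels' protocols, non-adherent marrow cells taken after 24 h of culture were grown with the growth factor M-CSF at 50 ng/mL for 72 h, giving bone marrow macrophages (BMM). These were treated with M-CSF at 30 ng/mL and the osteoclast-inducing cytokine RANKL at 100 ng/mL, for 24 h to give preosteoclasts (pOC) and for at least 72 h to give mature osteoclasts (mOC). The libraries have no replicates, so differences between stages have no replicate check and were not tested.

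The authors deposited 3 tables of CG regions, each comparing a pair of libraries (pOC against BMM, mOC against BMM and mOC against pOC). The table headings name time points rather than stages, and were matched to the stages by their hours. Regions shared between tables had identical read counts in the library they share, in 17128, 82392 and 17210 of as many regions. Per the file headers, each region has its position, the deposited counts of methylated reads and of all reads in both libraries (summed over its cytosines), the methylation level as a fraction, the number of cytosines and a p-value. Per the submitters' processing notes, the build was GRCm38, and FastQC, HISAT2 and StringTie were named with no version and no role. The bisulfite aligner, the region caller and its test are not given in the sources used here. Totals of reads per library are not analysed here, since the tables hold only listed regions.

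The deposited tables were checked against their own values. Each listed region had a difference of at least 20 percentage points, at least 4 cytosines and on average at least 4 reads per cytosine in both libraries, hence at least 16 reads. Regions were built from 200 bp bins. The authors' deposited p-value had the same order as a score test of the 2 levels computed from the deposited counts (Spearman correlation 1 over the regions of each table), and its size equalled that of a Benjamini-Hochberg adjustment over 303062, 103491 and 226632 regions (pOC against BMM, mOC against BMM and mOC against pOC). In mOC against pOC that number equals the listed regions, so the adjustment ran over regions already chosen for a large difference. That table also went up to a p-value of 0.0917, with 45014 regions (19.9%) above 0.05, while the other tables stopped at 0.05.

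This order of steps affects the measurements. On data simulated from the depths of each comparison, 20000 regions with 200 changed by 50 points, adjusting over preselected regions made 49.6% (pOC against BMM), 49.1% (mOC against BMM) and 40.1% (mOC against pOC) of calls false. Adjusting over all regions gave 8, 9 and 8 false calls and recovered 80%, 80% and 75% of the changed regions. With changes of 30 points it recovered 13.5%, 17.5% and 15%. Simulated base levels were held to the middle of the range, where counting error is greatest, while median levels over the listed regions ran from 46.6% (pOC) to 80.0% (BMM). The shares of false calls therefore describe this simulation and are not an estimate for the deposited regions. Reads covering several cytosines also enter a region several times, so reads within a region are not independent, and intervals and p-values cover counting error only and are too narrow.

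Regions were used as deposited. A region was called higher or lower by the sign of the difference, which equalled the authors' direction in every region. Levels are methylated reads divided by all reads, with exact Clopper-Pearson 95% intervals, and differences have Newcombe 95% intervals. The Fisher's exact tests (two-sided) compare 2 libraries, not 2 conditions. A minimum of 10 reads was set before the data were examined and removed no region. Regions were assigned to genes by overlap with the gene span in a RefSeq gene table of GRCm38.p6 (49943 genes). That table was used without strand or exons, so promoters, exons and introns were not placed, and distances to the nearer gene end are given instead. Shared regions overlapped by at least 1 bp. Chance overlap was taken from 100 random placements on the same chromosomes, and from simulated libraries with no difference that share 1 library as the real ones do. In these the third library was drawn at the pooled level of the 2 libraries compared first, and so between them.

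The 16 gene lists (405 entries, of which 404 matched by symbol and 1 by an older symbol) were fixed before the data were examined. They covered osteoclast differentiation and function, negative regulators of osteoclastogenesis, RANK, NF-κB, MAPK and calcium signalling, macrophage identity, V-ATPase and lysosome, cell fusion and cytoskeleton, DNA methylation machinery, glycolysis and mitochondrial metabolism, imprinted genes, Hox genes, and markers of T cells, B cells, neutrophils, erythroid cells and megakaryocytes, stromal cells and osteoblasts, and dendritic cells. For each list, the number of members with a region and the share of its regions higher in the later stage were set as percentiles among 10000 random lists of the same size, matched on gene length in deciles. Random lists were drawn from 34614 protein-coding and long non-coding RNA genes, and gene type was not matched. Percentiles describe these libraries and are not tests between stages.

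The genes named were chosen by a rule fixed before the data were examined. For each comparison they were up to 20 members of the 2 osteoclast lists, ordered by the size of the difference, then the 5 genes with the greatest gain and the 5 with the greatest loss, and the 3 genes with the most regions. Predicted genes were skipped in the last 2 groups. The rule put promoter regions first. Promoters could not be placed, so all regions in a gene were used. Each gene is given by its region with the greatest difference. Where a gene held several regions, this choice favours differences that are too large. Neither the intervals nor the p-values allow for it, or for the listing of regions by size of difference. Genes named outside this rule were chosen after their values were seen, and the text says so.

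Alternatives fixed in advance were a difference of at least 30 points, a deposited p-value of at most 0.001, regions in genes only, autosomes only, at least 10 cytosines, CG context only, weighting by cytosines, a reciprocal overlap of 50%, shares of base pairs, random lists without matching, minimum reads of 5 and 20, and unweighted means and medians. Alternatives added after seeing the data were a deposited p-value of at most 0.05 in every table, reads counted once per strand and region (reads scaled by 2 over the number of cytosines), Fisher's exact test with adjustment over the listed regions, removal of regions with over 3 times the median reads, and regions within 2000 bp of either gene end. With reads counted once, regions were kept at a score test p-value of at most 0.05 without adjustment. Those counts are thus not on the footing of adjusted p-values. The calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, with figures from matplotlib 3.10.9.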

Results

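DNA methylation at CG cytosines was compared between 3 stages of mouse osteoclast differentiation in culture: bone marrow macrophages (BMM), preosteoclasts (pOC, 24 h of RANKL) and mature osteoclasts (mOC, at least 72 h of RANKL). Osteoclasts are the multinucleated cells that resorb bone. Each stage had 1 library, so no difference between stages has a replicate check, and the p-values below compare the reads of 2 libraries. The authors' tables listed 251946 regions for pOC against BMM, 69337 for mOC against BMM and 226632 for mOC against pOC. Median depth per region ran from 31 to 37 reads summed over cytosines, or 5.6 to 6.5 reads per cytosine, so a typical single region carries wide counting error. Coordinates are those of GRCm38, and all named regions overlap the annotated span of their gene, with exon or intron not assigned.

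The first comparison asked how methylation differed after 24 h of RANKL. Listed regions in genes of osteoclast differentiation and function were mostly lower in pOC than in BMM, as were 92.9% of all listed regions. Of 35 list members, 31 held a listed region, 29 of them only regions lower in pOC, 2 regions in both directions and 0 only regions higher in pOC. Nfatc1, the master transcription factor of osteoclast differentiation, had 8 regions, all lower, and its region on chromosome 18 (80684801 to 80685000) was at 93.5% (95% interval 78.6 to 99.2, 31 reads) in BMM and 47.6% (32.0 to 63.6, 42 reads) in pOC. Mitf, a transcription factor that acts with it, had 42 lower and 2 higher regions, with 100% (92.1 to 100, 45 reads) in BMM against 40.5% (25.6 to 56.7, 42 reads) in pOC on chromosome 6 (97883001 to 97883200). Ostm1, a subunit partner of the chloride transporter Clcn7 in the bone-resorbing membrane, had the most reads of these regions, summed over 26 cytosines in 400 bp. On chromosome 10 (42681801 to 42682200) it stood at 81.2% (73.5 to 87.5, 133 reads) in BMM and 27.0% (21.0 to 33.7, 200 reads) in pOC (Fisher's exact test of the 2 libraries, p = 4.1e-23). Reads covering several of these cytosines count several times, so that p-value is too small.

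Listed regions in other osteoclast genes went the same way. The difference was 66.2 points (95% interval 34.1 to 81.8) in Ppargc1b, a coactivator of mitochondrial biogenesis, 62.8 points (32.0 to 79.4) in Cd109 and 57.7 points (28.1 to 74.9) in Prdm1, a transcriptional repressor. It was 56.6 points (29.5 to 73.8) in Clcn7 and 48.6 points (19.4 to 67.8) in Tnfrsf11a, which encodes the RANK receptor. Src, a kinase of the sealing zone, stood at 53.3% (37.9 to 68.3, 45 reads) in BMM and 7.14% (1.5 to 19.5, 42 reads) in pOC. The differences in the integrin subunit Itgav and the transcription factor Tfec were 45.6 points (30.4 to 58.3) and 44.4 points (18.9 to 66.3). The greatest difference of Itgb3, the beta 3 integrin subunit, lay the other way, with 46.2% (26.6 to 66.6, 26 reads) in BMM and 93.8% (79.2 to 99.2, 32 reads) in pOC.

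Of the 20 genes on the list of negative regulators of osteoclastogenesis, 15 held a region, 12 of them only regions lower in pOC and 3 both. Membership of that list was fixed beforehand, and the role of each gene was not tested here. The number of genes with a region lay at percentile 70.02 of random lists matched on gene length and the share of higher regions at 5.72. Irf8, a transcription factor of the macrophage lineage, stood at 100% (93.0 to 100, 51 reads) in BMM and 48.6% (31.9 to 65.6, 37 reads) in pOC on chromosome 8 (120750001 to 120750200). Tnfrsf11b, which encodes the RANKL decoy osteoprotegerin, stood at 74.4% (58.8 to 86.5, 43 reads) and 16.2% (6.19 to 32.0, 37 reads). Foxo3 differed by 63.7 points (36.8 to 79.5), Foxo1 by 51.0 (23.2 to 71.2), the deubiquitinase Cyld by 49.4 (20.5 to 69.2), Rbpj by 49.3 (24.2 to 66.5), Eomes by 49.1 (23.4 to 67.9) and Lgr4 by 43.9 (28.1 to 56.2), each lower in pOC.

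The other lists related to this lineage shared the direction. Regions lower in pOC outnumbered higher ones by 436 to 14 in RANK, NF-κB, MAPK and calcium signalling (34 of 40 members with a region), by 149 to 3 in macrophage identity (15 of 24), by 102 to 4 in V-ATPase and lysosome (21 of 26), by 486 to 11 in cell fusion and cytoskeleton (34 of 38) and by 147 to 4 in DNA methylation machinery (15 of 21). In the osteoclast list 256 regions were lower and 3 higher, so 1.16% were higher, below the 4.98% median of random lists matched on gene length (percentile 0.36). Within 2000 bp of a gene end, an alternative chosen after seeing the data, the share lay on the other side, with 4 of 44 regions higher (9.09%, median of random lists 4.17%, percentile 90.1). The number of osteoclast members with a region lay at percentile 92.0. Over the 16 lists and 3 comparisons, 3 of 48 such percentiles of direction fell in the outer 5%, against 2.4 from chance alone, and 2 of the 48 were at least as far out as 0.36, against 0.35 from chance.

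The direction held across the genome. Of all 251946 regions, 234161 (92.9%) were lower in pOC and 17785 (7.06%) higher. The read-weighted mean level over these regions was 73.5% in BMM and 46.9% in pOC. The median difference was 29.4 points in lower regions (interquartile range 24.9 to 35.7) and 27.3 points in higher ones (23.5 to 32.3). With a deposited p-value of at most 0.001, 40344 regions were left. Counting reads once per strand and region, a strict assumption on the dependence of reads within a region, left 68647 at an unadjusted score test p-value of at most 0.05.

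Among genes with a symbol other than a predicted one, the greatest loss in pOC lay in Npm1, which encodes a nucleolar chaperone, with 100% (86.3 to 100, 25 reads) in BMM and 8.70% (1.07 to 28.0, 23 reads) in pOC on chromosome 11 (33156602 to 33156801). Phlpp1 differed by 90.9 points (64.0 to 97.5), the DNA repair gene Ercc4 by 90.5 (64.8 to 97.3), Snd1 by 88.9 (59.8 to 96.9) and Mgat4a by 87.5 (57.0 to 96.5). The greatest gain among them lay in Cacna2d1, a calcium channel subunit gene, with 4.76% (0.12 to 23.8, 21 reads) in BMM and 77.8% (52.4 to 93.6, 18 reads) in pOC. It was 68.5 points (42.4 to 82.0) in Lrp1b, 66.0 (33.8 to 81.7) in Psmd11, 65.8 (34.8 to 80.8) in Sema5a and 65.7 (36 to 80.8) in Vps13a. The long genes Pde4d, Lrba and Hdac9 held the most regions, 274, 197 and 161, of which 270, 195 and 154 were lower in pOC.

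Listed regions lay in genes in 61.1% of cases, while 46.0% of 200 bp steps of the genome lie in genes, though the steps with enough reads to be listed were not analysed here. Regions in genes were less often higher in pOC (5.17%) than regions outside genes (10.03%). The share higher in pOC was 9.18% in regions with 4 to under 6 cytosines per 200 bp, 3.32% in those with 10 to under 20 and 4.97% in the 725 regions with 20 or more. It was 31.8% of 173 regions on chromosome Y, 15.2% on chromosome X and 6.96% on the autosomes. Of 21887 protein-coding genes, 14713 held at least 1 listed region.

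**Figure D1:**
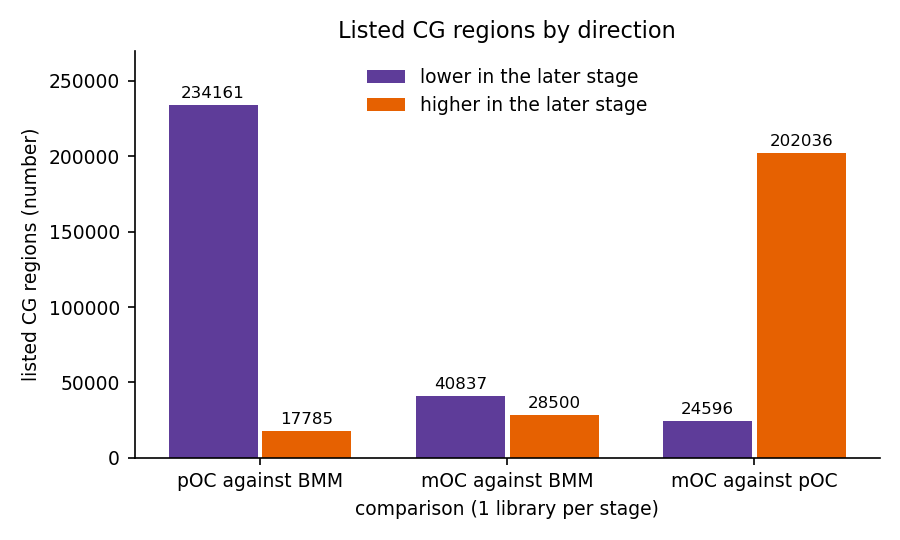
Number of listed CG regions (vertical axis) in each comparison of 2 libraries (horizontal axis), with 1 bar for regions less methylated and 1 for regions more methylated in the later stage. Lower regions prevail in pOC against BMM (234161 to 17785), higher ones in mOC against pOC (202036 to 24596), and the counts are nearer each other in mOC against BMM (40837 to 28500). Regions of mOC against pOC go up to a deposited p-value of 0.0917, those of the other comparisons up to 0.05.

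The second comparison followed the step from pOC to mOC, and the direction was the opposite, with 89.1% of all listed regions higher in mOC. Of 35 osteoclast genes, 32 held a region, 24 of them only regions higher in mOC, 8 both and 0 only lower ones. Ctsk, which encodes the collagen-degrading protease cathepsin K, stood at 45.1% (31.1 to 59.7, 51 reads) in pOC and 87.5% (75.9 to 94.8, 56 reads) in mOC on chromosome 3 (95502801 to 95503000). Cd109 stood at 23.5% (6.81 to 49.9, 17 reads) and 92.3% (74.9 to 99.1, 26 reads) on chromosome 9 (78679001 to 78679200), the same region that was lower in pOC than in BMM, by the same pOC reads. In Mitf 37 regions were higher and 2 lower in mOC, with 36.7% (19.9 to 56.1, 30 reads) in pOC and 86.7% (73.2 to 94.9, 45 reads) in mOC on chromosome 6 (97880401 to 97880600).

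In further osteoclast genes the region of greatest difference was higher in mOC than in pOC. The difference was 60.4 points (28.6 to 78.2) in Ostm1, 54.9 (21.9 to 73.9) in Ppargc1b, 52.9 (25.7 to 73.8) in Src, 52.8 (22.8 to 71.2) in Tnfrsf11a, 48.3 (23.9 to 67.2) in the RANK adaptor gene Traf6 and 48.2 (16.9 to 69.4) in Slc9b2. It was 46.7 points (16.6 to 68.5) in Car2, which encodes carbonic anhydrase 2, 46.2 (15.6 to 68.1) in Clcn7, 45.2 (28.2 to 59.1) in Itgb3, 44.7 (16.8 to 65.3) in Jdp2 and 41.6 (13.2 to 60.1) in the calcitonin receptor gene Calcr. On the list of negative regulators, 14 of 20 genes held a region, 7 only higher, 2 only lower and 5 both. Zbtb46 was higher by 51.8 points (19.96 to 71.3), Rbpj by 48.4 (23.0 to 67.9), Tnfrsf11b by 46.3 (23.5 to 63.2), Foxo3 by 46.0 (17.3 to 65.4), Lgr4 by 43.6 (18.3 to 61.5) and Foxo1 by 41.5 (23.4 to 57.1).

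Regions higher in mOC outnumbered lower ones by 206 to 11 in the osteoclast list, by 309 to 20 in RANK, NF-κB, MAPK and calcium signalling (32 of 40 members), by 121 to 13 in macrophage identity (16 of 24), by 77 to 5 in V-ATPase and lysosome (20 of 26) and by 388 to 29 in cell fusion and cytoskeleton (36 of 38). In DNA methylation machinery, 118 regions were higher and 2 lower (17 of 21 members), a share of 98.3% higher at percentile 99.9 of random lists (88.0 at a difference of at least 30 points and 88.6 near gene ends). The number of osteoclast genes with a region lay at percentile 97.6, and their share of higher regions, 94.9%, at percentile 95.9 (45.9 near gene ends, with 92.7% against a median of 93.2%). Over all lists and comparisons, 1 of 48 percentiles of the number of genes fell in the outer 5%, against 2.4 from chance alone.

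Of all 226632 regions, 202036 (89.1%) were higher in mOC and 24596 (10.9%) lower. The mean level was 45.6% in pOC and 69.6% in mOC, with a median difference of 27.9 points in higher regions (23.8 to 33.9) and 25.8 in lower ones (22.7 to 30.3). At a deposited p-value of at most 0.05, as in the other tables, 181618 regions were left. At 0.001, 20638 were left, and 43305 when reads were counted once per strand and region, at an unadjusted score test p-value of at most 0.05.

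Among such genes Ube4a, a ubiquitin ligase gene, had the greatest gain in mOC over pOC, with 0% (0 to 9.25, 38 reads) in pOC and 91.8% (80.4 to 97.7, 49 reads) in mOC on chromosome 9 (44960401 to 44960600). The gain was 90.9 points (64.6 to 97.5) in Tbc1d5, 88.5 (67.5 to 96.0) in Cep95, 88.0 (67.1 to 95.8) in Spock3 and 87.5 (58.1 to 96.5) in Niban1. The greatest loss among them lay in the transcription factor gene Foxp1, with 86.7% (69.3 to 96.2, 30 reads) in pOC and 17.6% (3.80 to 43.4, 17 reads) in mOC on chromosome 6 (99454601 to 99454800). Losses were 68.8 points (35.8 to 84.4) in Esrrg, 68.3 (39.8 to 83.9) in Mipol1, 66.7 (40.8 to 83.7) in Boll and 66.4 (37.1 to 81.2) in Unc79. Pde4d, Wwox and Lrba held the most regions, 210, 166 and 152, of which 195, 156 and 144 were higher in mOC.

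Regions in genes made up 58.4% of this table, and 91.1% of them were higher in mOC, against 86.4% of regions outside genes. The share lower in mOC was 29.2% of 171 regions on chromosome Y, 19.8% on chromosome X and 10.7% on the autosomes.

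The third comparison set the end of differentiation against its start, and mOC and BMM differed in fewer regions and in both directions. Of 35 osteoclast genes 22 held a region, 10 only lower in mOC, 3 only higher and 9 both. Spi1, which encodes the myeloid transcription factor PU.1, stood at 46.2% (35.6 to 56.9, 91 reads) in BMM and 9.68% (3.63 to 19.9, 62 reads) in mOC on chromosome 2 (91106002 to 91106201). Car2 stood at 46.7% (35.0 to 58.6, 75 reads) and 13.3% (5.94 to 24.6, 60 reads) on chromosome 3 (14890601 to 14890800). Nfatc1 had 4 regions, all lower in mOC, among them 1 on chromosome 18 (80711001 to 80711200), 1871 bp from a gene end, with 89.4% (76.9 to 96.5, 47 reads) in BMM and 54.2% (32.8 to 74.4, 24 reads) in mOC.

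Differences toward a lower level in mOC were 50 points (25 to 69.1) in Cd109, 40.7 (16.3 to 58.9) in Snx10, 40.5 (22.2 to 55.3) in Ostm1, 34.4 (7.31 to 56.3) in Mitf, 32.1 (10.7 to 50.8) in Traf6, 31.9 (12 to 47.1) in Ppargc1b, 31 (5.97 to 50.5) in Prdm1, 31.9 (9.72 to 50.2) in the fusion gene Dcstamp and 31.6 (13.6 to 49.1) in the proton pump subunit gene Atp6v0d2. Itgb3 was higher in mOC by 38.4 points (5.94 to 61.5). Each value is that of 1 region, and some of these genes were mixed. Higher and lower regions numbered 3 and 4 in Cd109, 1 and 1 in Ostm1, 2 and 7 in Mitf, 1 and 3 in Ppargc1b and 3 and 2 in Itgb3. Snx10, Traf6, Prdm1, Dcstamp and Atp6v0d2 held only lower ones. On the list of negative regulators 9 of 20 genes held a region, 2 only lower, 4 only higher and 3 both. At its region of greatest difference, Foxo3 was lower by 45.3 points (15.8 to 66.6), Eomes by 40.6 (12.9 to 59.3) and Foxo1 by 30.6 (13.3 to 48.0), and Zbtb46 was higher by 36 (5.2 to 58.7), Lgr4 by 33.2 (13.1 to 48.8), Rbpj by 31.7 (5.45 to 49.9) and Rgs12 by 31 (7.57 to 50.5). Regions of Rbpj went both ways (3 higher and 4 lower), as did those of Zbtb46 and Foxo3 (1 and 1 each). All regions of Eomes, Foxo1, Lgr4 and Rgs12 had the direction given. With reads counted once per strand and region, the strict assumption, 11 of the 33 regions named for this comparison had an unadjusted p-value above 0.05, those of Atp6v0d2, Dcstamp, Itgb3, Lgr4, Mitf, Ppargc1b, Prdm1, Rbpj, Rgs12, Spi1 and Zbtb46.

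The osteoclast list held 17 regions higher and 43 lower in mOC than in BMM (28.3% higher, percentile 8.81 of random lists). Higher and lower regions numbered 33 and 58 in RANK, NF-κB, MAPK and calcium signalling (29 of 40 members), 19 and 21 in macrophage identity (14 of 24), 6 and 15 in V-ATPase and lysosome (11 of 26), 43 and 70 in cell fusion and cytoskeleton (25 of 38) and 7 and 21 in DNA methylation machinery (12 of 21).

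Of all 69337 regions, 40837 (58.9%) were lower in mOC and 28500 (41.1%) higher. The mean level was 59.6% in BMM and 54.3% in mOC, and the median difference 27.5 points in each direction. At a deposited p-value of at most 0.001, 1283 regions were left, of which 73.2% were lower in mOC. With reads counted once per strand and region, 11443 were left at an unadjusted score test p-value of at most 0.05.

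Among such genes Foxp1 also had the greatest loss from BMM to mOC, in the same region and by the same mOC reads, with 100% (81.5 to 100, 18 reads) in BMM and 17.6% (3.80 to 43.4, 17 reads) in mOC. Losses were 75.4 points (43.2 to 88.5) in Mtus2, 75 (51.4 to 87.3) in Def8, 74.7 (45.5 to 87.0) in the cartilage collagen gene Col2a1 and 72.1 (42.4 to 85.0) in Lsamp. The greatest gain among them lay in Gldc, which encodes a glycine-cleaving enzyme, with 31.2% (11.0 to 58.7, 16 reads) in BMM and 100% (80.5 to 100, 17 reads) in mOC. Gains were 68.7 points (38.1 to 83.2) in Trank1, 67.5 (38.5 to 81.9) in Diaph2, 65.4 (33.2 to 81.5) in Nmur1 and 65.0 (40.0 to 78.9) in Tex11. The immunoglobulin kappa locus Igk, Pde4d and Tenm3 held the most regions, 62, 57 and 54, of which 35, 17 and 33 were higher in mOC. Regions in genes made up 54.8% of the table, and 37.7% of them were higher in mOC, against 45.2% outside genes.

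The 3 libraries were then followed through the same regions. At identical coordinates, 82392 regions were listed at both steps, and 78666 of them (95.5%) were lower in pOC than in BMM and higher in mOC than in pOC. Their median level was 81.9% in BMM, 46.4% in pOC and 80.4% in mOC. The median of mOC minus BMM was -1.05 points there (interquartile range -6.25 to 3.80), and 1294 of these regions were also listed for mOC against BMM. In 3588 regions (4.35%) pOC was above both others, with medians of 23.7%, 55.9% and 25%. Levels were lower at both steps in 95 regions (87.0%, 60.9% and 34.6%) and higher at both in 43 (14.3%, 44.4% and 71.4%).

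**Figure D2:**
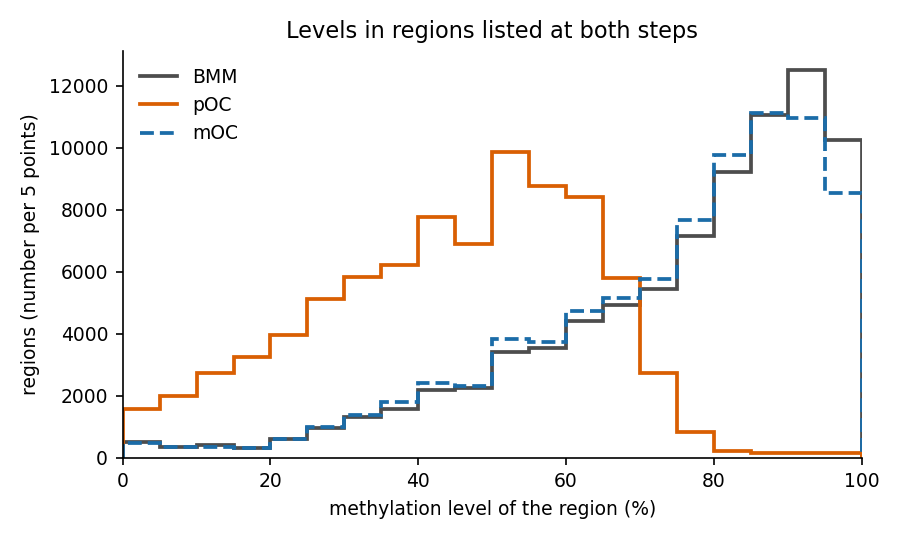
Number of regions (vertical axis, per 5 percentage points) by methylation level in percent (horizontal axis) in the BMM, pOC and mOC libraries, over the 82392 regions listed at both steps. BMM and mOC lie nearly on each other at high levels and pOC lies lower, in regions chosen because pOC differed from each of the others.

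Of the regions listed for pOC against BMM, 37.2% overlapped one listed for mOC against pOC, where random placement gave 2.10%. Opposite directions are expected there, since the tables share the pOC library: the same direction was found in 0.168% of overlapping regions of 200 bp, and in 0.0567% in simulated libraries with no difference. Among regions of 200 bp the overlap was 35.5%, and simulated libraries with no difference that share the pOC library gave 26.3%. There mOC was drawn at the pooled level of BMM and pOC, not at a level of its own. That level lies between BMM and pOC, so 26.3% is not what the shared pOC library alone would give. How much of the observed overlap came from sharing a library was not settled. Overlap of pOC against BMM with mOC against BMM was 7.77% (random placement 0.62%). Among regions of 200 bp it was 7.40%, against 18.9% in simulation. As mOC was again drawn between BMM and pOC, and not at the BMM level, 18.9% is not what the shared BMM library alone would give. Overlap of mOC against BMM with mOC against pOC was 26.9% (random placement 1.99%), with 26.7% observed and 23.8% simulated among regions of 200 bp. In that simulation pOC was drawn at the pooled level of BMM and mOC, so the same limit holds for 23.8%. Independent lists would share 111232 regions that were lower in pOC and then higher in mOC, given the 425317 regions listed anywhere, against 89998 observed. That number takes only listed regions as its background.

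**Figure D3:**
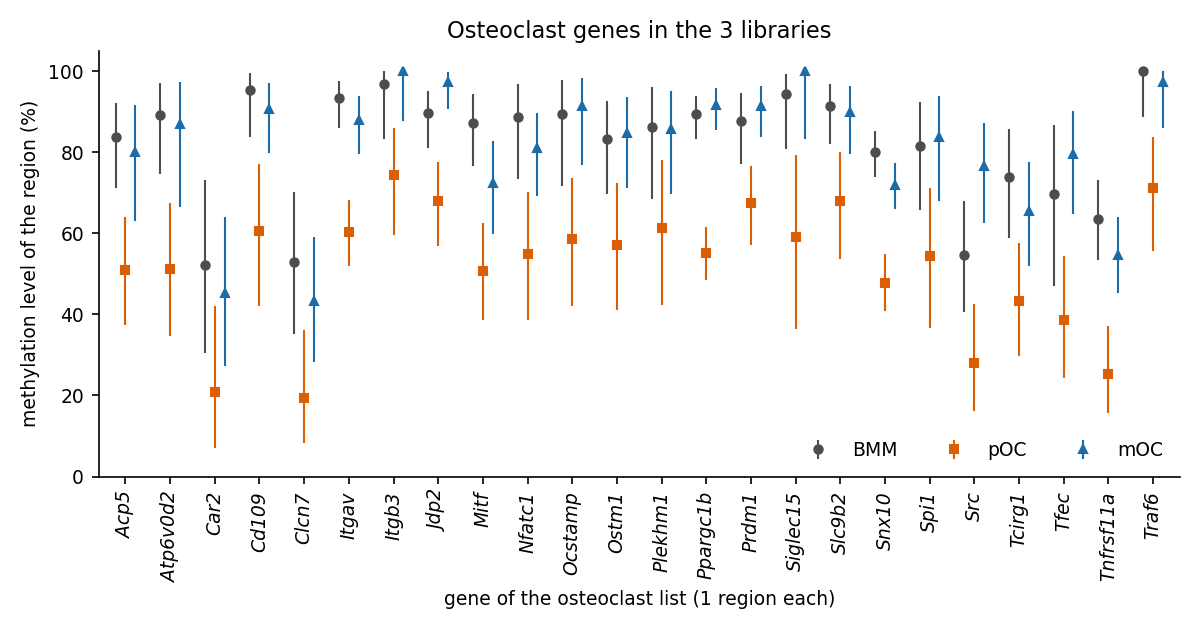
Methylation level in percent (vertical axis) with exact 95% intervals in BMM, pOC and mOC for the 24 osteoclast genes with a region listed at both steps (horizontal axis), 1 region per gene, the one with the most reads. All 24 are lower in pOC, with medians of 87.5% in BMM, 54.9% in pOC and 85.2% in mOC, in regions chosen for a difference at both steps.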

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

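Reads counted once per strand and region, Fisher's exact test with adjustment, removal of regions with over 3 times the median reads, a deposited p-value of at most 0.05 and regions near gene ends were chosen after seeing the data. Over all listed regions, the prevailing direction of each comparison was the same under each alternative run, while 5 values of gene lists reversed. The median region had 31 to 37 reads that are not independent, and the cause of the shifts below was not tested. No paired analysis was possible because each stage had 1 library. Alternatives on promoters (a narrower promoter, and promoter regions alone for the gene lists) were not run, since the gene table was used without strand. CG context only and a minimum of 5 reads removed no region.

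Counts by comparison follow in the order pOC against BMM, mOC against BMM and mOC against pOC. Fewer regions pass stricter rules by construction. A difference of at least 30 points left 117298, 25652 and 87397 regions, a deposited p-value of at most 0.001 left 40344, 1283 and 20638, regions in genes numbered 153994, 37981 and 132363, and at least 10 cytosines left 41207, 7802 and 28447. Reads counted once per strand and region left 68647, 11443 and 43305 at an unadjusted score test p-value of at most 0.05. Fisher's exact test with adjustment left 146775 for mOC against pOC and stayed within 1.5 times the deposited count in the others.

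The share of regions lower in the later stage, deposited at 92.9%, 58.9% and 10.9%, was 98.8%, 73.2% and 2.01% at a deposited p-value of at most 0.001, 94.8%, 62.3% and 8.90% in genes, 97.5%, 63.2% and 4.09% with at least 10 cytosines and 96.0%, 62.7% and 5.53% with reads counted once per strand and region. For pOC against BMM and mOC against pOC it was 94.7% and 7.50% at 30 points, 93.6% and 7.63% with Fisher's exact test, and 92.8% and 11.0% without regions of over 3 times the median reads. It was 93.0% on autosomes for pOC against BMM, and 9.08% for mOC against pOC at a deposited p-value of at most 0.05. Gene lists and overlaps were not rerun at that threshold.

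The median signed difference (later minus earlier stage, deposited at -28.7, -22.3 and 26.8 points) was -28.1, -22.1 and 26.7 when weighted by cytosines and -37.1, -31.3 and 37.8 at a deposited p-value of at most 0.001. The share of base pairs in genes was 61.7% for pOC against BMM and 58.8% for mOC against pOC. With at least 20 reads, mean levels were 73.6% (BMM) and 47.2% (pOC), 59.8% (BMM) and 54.5% (mOC), and 45.9% (pOC) and 69.9% (mOC). Unweighted means were 73.0% and 46.0%, 58.9% and 53.8%, and 44.8% and 68.6%, and medians 80.0% and 48.6%, 62.1% and 55.8%, and 46.6% and 73.9%.

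Overlap of pOC against BMM with mOC against pOC was 36.9% with a reciprocal overlap of 50% and 28.7% at 30 points. At 30 points overlap with mOC against BMM was 4.26%, and that of mOC against BMM with mOC against pOC 17.8%. Osteoclast genes with a region in mOC against BMM numbered 12 near gene ends and 14 at 30 points. Without matching on gene length, the percentile of osteoclast genes with a region was 99.96 for pOC against BMM and 99.7 for mOC against BMM, against 92.0 and 86.0 with matching on length but not on gene type, so such matching lowered these values. With matching, it was 97.6 for mOC against pOC, at 30 points 98.97 for pOC against BMM, 82.5 for mOC against BMM and 99.85 for mOC against pOC, and near gene ends 82.75, 95.4 and 97.4 in that order. Of 99 named regions, Fisher's exact test left each on its side of 0.05, and counting reads once put 11 above it, all in mOC against BMM.

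Directions within gene lists moved more, on few regions. Near gene ends the share of osteoclast regions higher in pOC than in BMM was 9.09% (4 of 44), and its percentile among random lists reversed from 0.36 to 90.1, while at 30 points the percentile was 2.74. In mOC against BMM the share higher was 50% near gene ends (7 of 14) and 13.0% at 30 points (3 of 23, percentile 1.02), against 28.3%. In mOC against pOC it was 97.8% at 30 points (percentile 93.4) and 92.7% near gene ends (percentile 45.9), against 94.9%. Shares higher in mOC than in BMM reversed near gene ends in macrophage identity (62.5%, 5 higher and 3 lower), glycolysis and mitochondrial metabolism (57.1%, 4 and 3) and neutrophil markers (42.9%, 3 and 4), and at 30 points in erythroid and megakaryocyte markers (100%, 1 and 0).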

Other observations

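Gene groups outside the osteoclast lineage had the prevailing direction of the genome at both steps. In pOC against BMM, regions lower in pOC outnumbered higher ones by 217 to 7 in glycolysis and mitochondrial metabolism (26 of 32 genes with a region), 257 to 12 in imprinted genes (22 of 31), 35 to 0 in Hox genes (17 of 39), 88 to 2 in T cell markers (13 of 16), 9 to 0 in neutrophil markers (6 of 16), 23 to 1 in erythroid and megakaryocyte markers (8 of 16), 131 to 2 in stromal and osteoblast markers (16 of 20) and 162 to 2 in dendritic cell markers (10 of 14). B cell markers had the greatest share of higher regions of these lists, with 12 of 93 (12.9%, percentile 96.2 of random lists, but 85.8 at 30 points with 3 of 36 and 24.1 near gene ends with 0 of 17), 6 of the 12 in Ebf1, an early B cell transcription factor gene that also held 35 lower regions. Runx2, the master regulator of bone-forming cells, held 77 lower regions and 0 higher ones, and the dendritic transcription factor gene Tcf4 107 lower and 2 higher. These 3 genes were named after their values were seen.

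In mOC against pOC, higher regions outnumbered lower ones by 183 to 14 in glycolysis and mitochondrial metabolism (27 of 32 genes), 231 to 29 in imprinted genes (22 of 31), 33 to 3 in Hox genes (16 of 39), 74 to 9 in T cell markers (13 of 16), 74 to 4 in B cell markers (11 of 16), 10 to 1 in neutrophil markers (4 of 16), 27 to 0 in erythroid and megakaryocyte markers (7 of 16), 113 to 12 in stromal and osteoblast markers (15 of 20) and 119 to 6 in dendritic cell markers (12 of 14). In mOC against BMM, higher and lower regions numbered 16 and 34 (glycolysis and mitochondrial metabolism, 16 genes), 36 and 38 (imprinted, 15), 3 and 7 (Hox, 7), 5 and 16 (T cell, 10), 12 and 15 (B cell, 6), 3 and 2 (neutrophil, 3), 2 and 3 (erythroid and megakaryocyte, 2), 12 and 20 (stromal and osteoblast, 11) and 6 and 11 (dendritic, 5).

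Tests on the p-value threshold, counting noise, repeated sequence and the number of libraries were chosen after the result was seen, and the others before. The pOC library was less methylated than BMM and mOC at most listed regions, and regions with a deposited p-value above 0.05 made up 19.9% of mOC against pOC, fewer than the 72.9% needed to raise the share higher in mOC from 60% to that seen, which argues against the differing thresholds as the whole cause. The share lower in pOC than in BMM was 92.9% where pOC had more reads and 93.1% where it had fewer (against depth) and 98.9% of the 1424 regions with p of at most 0.001 and reads counted once (against counting noise). Repeated sequence stays open: the share was 92.8% without the 6011 regions of over 3 times the median reads, but these were too few to bring it under 60% whatever their direction. One uniform proportional drop of the pOC library stays open too. It was examined only in 3966 regions with many reads in both libraries and a high BMM level. Regions higher in pOC than in BMM had a median BMM level of 23.7%, so most of them lay outside that set. Within it, levels scattered around 1 common ratio with a dispersion of 0.257, within the bound of 1.5 set beforehand for such a drop. That bound decides little, as a check added afterwards showed: with the same listing rule, simulated uniform drops gave 0.609 to 0.655, above the observed value, so the counting error assumed was too large, while uneven drops (SD 0.2) gave 1.37 to 1.58 and every read counted gave an observed 2.15. With 1 pOC library, a change of the cells and a fault of that library, such as bisulfite conversion of methylated cytosines, cannot be told apart.

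Regions higher in pOC than in BMM were more frequent on chromosome X (15.2%) than on the autosomes (6.96%). Autosomal regions drawn with the same reads and cytosines reached at most 9.14% in 100 draws, below the 15.2% of 2659 X regions, which argues against lower depth as the whole cause. With the mean level of both libraries matched as well they reached at most 11.7%, against 15.2% of 2651 X regions, which argues against a lower level as the whole cause. The share was 31.8% in the 173 regions of chromosome Y, so X was not alone. The sex of the animals is not given in the sources used here, and although regions of chromosome Y were listed in every comparison (173, 74 and 171), so that each library held reads placed there, whether repeated sequence accounts for them was not tested.

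A hypothesis was that losses kept to the mature stage may concentrate in osteoclast genes. It was not borne out by the number of osteoclast genes with such a loss. Direction is a separate measure: the share of osteoclast regions higher in mOC than in BMM lay at percentile 8.81, at 1.02 with 30 points and at 72.2 near gene ends. Of 35 osteoclast genes, 1 (Spi1) held a loss from BMM to mOC at a deposited p-value of at most 0.001, at percentile 53.5 of random lists matched on gene length. The median of those lists was 1 gene, so this percentile rests on few genes. Regions lower than BMM in both pOC and mOC lay in 11 osteoclast genes, Atp6v0d2, Car2, Cd109, Clcn7, Itgav, Mitf, Ppargc1b, Snx10, Spi1, Tfec and Traf6, at percentile 80.9. Both comparisons use the same BMM reads, so a BMM level high by counting error alone can place a region in this set. In Car2 such a region was at 46.7% in BMM (75 reads), 10.4% in pOC (67 reads) and 13.3% in mOC (60 reads), and in Spi1 at 46.2% (91 reads), 26.2% (65 reads) and 9.68% (62 reads). Cell fusion and cytoskeleton genes held 4 of the clearest losses (Cd47, Myo10, Myo1e and Vcl, percentile 96.3), 1 of 32 such percentiles computed, in genes named after their values were seen.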
